A study of Physcomitrium patens with 4 samples.

How the data were processed

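Messenger RNA was measured by sequencing in 4 libraries of the moss Physcomitrium patens (ecotype Gransden2004). Per the labels, the tissue was chloronema of the protonema, the filamentous stage that grows from a moss spore. The cultures were 10 days old and spent 3 days in the dark. Red light was given for 1 hour from a 660 nm source at 5 μmol per square metre per second and 25 °C. The groups were wild type in the dark, wild type after red light, the pubs hy2 double mutant in the dark and pubs hy2 after red light, with 1 library per group. The labels call the dark libraries time 0 controls. Per the labels' protocols, poly-A RNA was selected, fragmented for 4 minutes at 94 °C, copied by random priming, ligated to barcoded adapters, size-selected at 200 to 400 bp, amplified by 18 PCR cycles and pooled. The protocol states no step that keeps the strand of origin, so reads from overlapping genes on opposite strands were treated as not separable. The reads carry no molecular identifiers, so PCR copies could not be told from separate molecules. All intervals and floors given here cover the counting error of reads only.

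The authors deposited an estimated count of reads for each of 32273 genes in each library, in a column headed as reads per the file headers. About 95% of these values were whole (95.4% to 95.6% per library, counted as exactly whole), and the rest carried decimals, so the estimated counts were rounded to whole numbers here. The authors also deposited an RPKM value per gene (reads scaled by gene length in kilobases and by the library total). Dividing the reads by the length and the RPKM gave a nearly constant total within each library, by which the reads summed over genes fell short by 10.5% to 12.6%. The files further hold the authors' share of a gene's reads that map to several places, a fraction from 0 to 1 per the file headers, and a gene length in kilobases. Of these lengths 66.7% were multiples of 3 base pairs, more than unselected lengths would give and fewer than coding lengths alone. The aligner, the way multi-mapping reads were shared out, the genome build and the gene annotation version were not given in the sources used here.

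The reads summed over genes were 17560594 in the wild-type dark library, 24560044 in the wild-type red light library, 15098942 in the pubs hy2 dark library and 22975721 in the pubs hy2 red light library. Libraries were scaled by TMM factors (edgeR 4.0.16 in R 4.3.3), which were 1.04, 1.02, 0.969 and 0.973 in that order. The floor, set at 3 counts per library, corresponded to 0.164, 0.120, 0.205 and 0.134 on the scaled CPM scale.

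With 1 library per group no replicate error exists. A size rule was therefore fixed before the data were examined and no p-value was computed for these comparisons. A gene was counted as differing when its fold between 2 libraries was at least 2 and the exact 95% counting interval of that fold (Clopper-Pearson on the share of the reads, scaled by library size) excluded 1. Genes needed at least 50 reads in the libraries compared and are called measured. For the difference of the red light response between genotypes, the fold in pubs hy2 was divided by the fold in wild type. The same limits were applied to this ratio, with an interval on the log scale after adding 0.5 to each count. For single genes the exact conditional interval of the odds ratio is given. Such rules compare libraries, not conditions. Where a gene had 0 reads in 1 library, its fold was computed against the floor of 3 counts in that library and is a bound. Genes were ranked with these bounds, so a gene with 0 reads can have a larger difference than its rank shows. Log2 folds over lists were computed after adding 0.5 to each count, with genes at 0 in 1 library set to that bound.

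A model with the terms genotype and light was fitted to all 4 libraries with edgeR's quasi-likelihood test, after its expression filter and with Benjamini-Hochberg adjustment at 0.05. It sets 2 libraries against 2, leaves 1 residual degree of freedom and tests only effects that are alike in both genotypes or both light conditions. DESeq2 1.42.0 and limma 3.58.1 were run with the same model as alternatives. Other alternatives changed the library scaling, the minimum reads, the fold, the depth and the source of the values. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

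After the data were examined, a set of 30696 singly mapped genes was added, defined by a multi-mapping share under 10% in every library. Counts are given for all genes and for this set.

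The size rule was tested on simulated data. For red light against dark in wild type, 97 of 100 genes changed 2.5-fold and 100 of 100 genes changed 4-fold were recovered, with 12 false calls among 18736 genes. For the difference of red light folds, 96 of 100 and 100 of 100 were recovered, with 129 false calls among 19836 genes. For red light against dark in pubs hy2, simulated with no change, 13 of 18532 genes were called. These simulations held counting error only. The additive fit, simulated with a coefficient of variation of 0.1, recovered 100 of 100 genes at each fold for both effects, with 6 false calls among 20299 genes for light and 5 among 20311 for genotype. The common coefficient of variation estimated in the real fit was larger, 0.239, and includes any difference of the light response between genotypes. Simulated at 0.25, the fit recovered 42 of 100 genes changed 2.5-fold for each effect. Of genes changed 4-fold it recovered 95 of 100 for light and 92 of 100 for genotype, with 4 and 5 false calls among 20354 and 20309 genes.

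The files do not pair gene identifiers with names, and 0 of the 32273 identifiers matched the reference gene table used here. None of the 29 gene lists fixed before the data were examined, which cover light signalling, photosynthesis, pigments, stress, growth and cell types, could therefore be given members, and none is reported. The transcripts of the mutated genes PUBS and HY2 were likewise not analysed here. The rule for named genes gave, without names, the 2 identifiers with the largest fold in each direction per comparison among genes passing the size rule with at least 100 reads. That rule did not cover pubs hy2 against wild type in red light, to which it was applied after the values were seen. In each direction the first of these is printed. The first by the same rule among singly mapped genes is printed beside it and was chosen after the values were seen; where both forms gave the same first gene, the second is printed too. The ranking for the difference of red light folds was changed after the values were seen, from ratios with 0.5 added to ratios with 0 reads set to the floor. The use of bounds in log2 folds over lists was added at the same stage.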

Results

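Transcripts were counted in 4 libraries of Physcomitrium patens protonema, the filamentous stage of the moss. Wild type and the pubs hy2 double mutant were each sampled in the dark and after 1 hour of red light, with 1 library per group. The dark libraries were time 0 controls per the labels, and no library was kept dark for the further hour. Differences between red light and dark below therefore cannot be told apart from effects of the elapsed hour. PUBS and HY2 encode bilin synthases, enzymes that make linear tetrapyrrole pigments such as the phytochrome chromophore, and the series describes the double mutant as deficient in phytochrome, the red light receptor. The design asked which transcripts differ after a short red light exposure, and which of these differences are altered in the mutant. Reads on genes ranged from 15098942 to 24560044 per library, and between 22398 and 23843 of the 32273 genes had at least 1 read. There was no replicate of any group, so no difference between 2 libraries below has a replicate check, and higher or lower refers to libraries, not to conditions. Genes carry identifiers without names in the files, so groups of genes are described by their response and not by function.

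The libraries resembled each other most within a genotype. Across 16318 singly mapped genes with at least 200 reads in all, the SD of the log2 fold between red light and dark was 0.70 in wild type and 0.48 in pubs hy2. Between the genotypes it was 1.14 in the dark and 1.14 in red light. The Spearman correlation of reads across these genes, which are not independent replicates, was 0.937 between the wild-type libraries and 0.967 between the pubs hy2 libraries. It was 0.851 between genotypes in the dark and 0.852 in red light. The most abundant gene of each library took 2.98% and 2.81% of the reads in wild type (dark and red light) and 1.15% and 1.17% in pubs hy2. The 10 most abundant genes took 11.0% and 9.74% in wild type and 6.39% and 6.94% in pubs hy2.

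**Figure D1:**
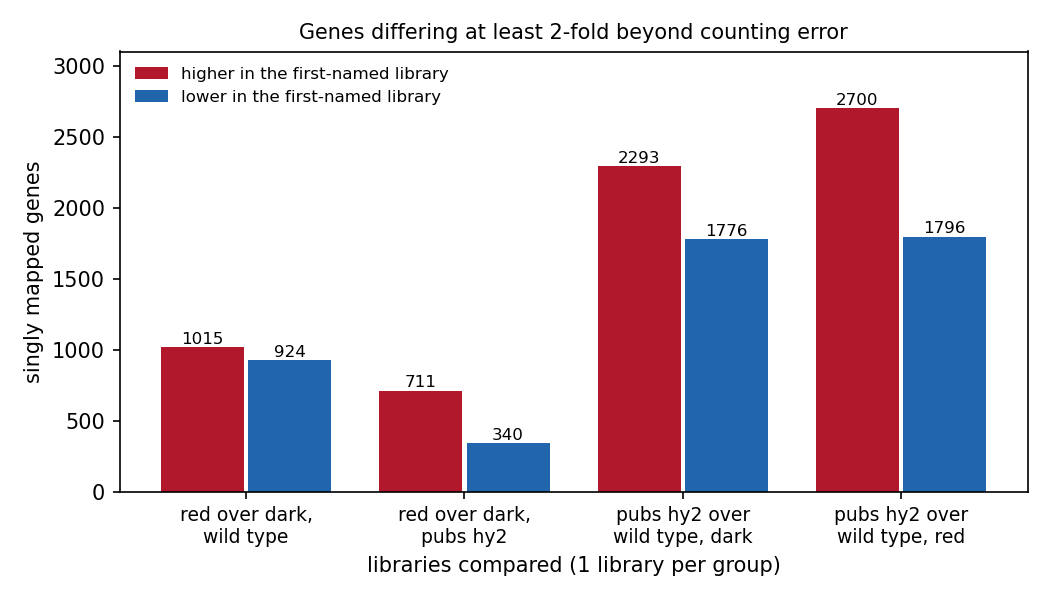
Bars give the number of singly mapped genes (y axis) that were higher (red) or lower (blue) in the first-named library of each pair (x axis), by at least 2-fold and beyond the 95% counting interval, with 1 library per group. The tallest pair of bars, 2700 higher and 1796 lower, is pubs hy2 over wild type in red light, and the shortest, 711 and 340, is red light over dark in pubs hy2.

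In wild type, 1110 genes were higher and 1005 were lower in the red light library than in the dark library, which together made 11.6% of 18303 measured genes. The split was near even under each scaling, but which side was larger depended on it. The authors' RPKM gave 992 higher and 1051 lower, and totals without the 100 most abundant genes and without TMM factors gave 1034 and 1105. Among singly mapped genes 1015 were higher and 924 lower of 17274. The median log2 fold was 1.48 for the singly mapped genes that were higher and -1.37 for those that were lower. At least 8-fold differences were found for 65 singly mapped genes that were higher and 36 that were lower. The singly mapped gene with the highest fold, Pp1s55_88V6, had 0 reads in the dark and 308 in red light, at least 75.4-fold higher in red light. In pubs hy2 it had 0 and 4 reads. The singly mapped gene with the lowest fold, Pp1s123_69V6, had 105 reads in the dark and 5 in red light, a fold of 0.0350 (95% counting interval 0.0111 to 0.0842).

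The genes that led when all genes were ranked drew nearly all of their reads from sequence shared with other genes. Pp1s85_186V6 had 0 reads after rounding in the wild-type dark library and 2739 in red light, at least 670.5-fold higher. In red light 99.9% of its reads were multi-mapping. A share of 100% was given for it in the dark, so its 0 there may be a fraction rounded down. Pp1s292_31V6 had 3711 reads in the dark and 0 in red light, at least 1684-fold lower, and 99.7% of its dark reads were multi-mapping. Of the 50 largest red light folds in wild type, 19 belonged to genes with at least 90% multi-mapping reads in a library, although such genes made up 1.33% of those measured. In pubs hy2 it was 27 of 50. The values of these genes are uncertain, because they depend on how shared reads were assigned.

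In pubs hy2, 782 genes were higher and 407 were lower after red light, 6.42% of 18531 measured genes. Among singly mapped genes, 711 and 340 of 17471 passed, with median log2 folds of 1.28 and -1.21. Folds of at least 8 were found for 14 singly mapped genes that were higher and 0 that were lower. The lower genes were mostly weakly expressed: when measured genes were put in 5 equal bins by mean expression, 241 of the 340 lay in the lowest bin and 8 in the highest, against 335 and 91 of the higher genes. In wild type the lowest bin also held the most genes of both kinds, 331 higher and 405 lower, and the highest bin held 225 and 138.

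Among singly mapped genes, Pp1s74_232V6 had the highest red light fold in pubs hy2, with 17 reads in the dark and 363 in red light, 14.0-fold higher (interval 8.60 to 24.2). Its fold in wild type was 2.56 (2.06 to 3.21). The lowest was that of Pp1s20_367V6, which had 215 and 72 reads, a fold of 0.219 (0.165 to 0.287). In wild type it had 440 and 28 reads, a fold of 0.0467 (0.0307 to 0.0685). Over all genes the ranking was again led by multi-mapping genes. Pp1s22_366V6 had 0 and 1273 reads, at least 277.6-fold higher, and Pp1s442_5V6 had 1292 and 0 reads, at least 658.4-fold lower.

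Genes that differed after red light in wild type differed in part in the same direction in pubs hy2. Of 912 singly mapped genes that were higher in wild type and measured in both genotypes, 256 were also higher in pubs hy2, where independent lists would share 34.4, and 20 were lower, where independent lists would share 14.2. Of 846 that were lower in wild type, 49 were also lower in pubs hy2, against 13.2 for independent lists, and 38 were higher, against 31.9. The counts for independent lists ignore expression level. In both genotypes the lowest expression bin held the most genes that differed, for lower genes 405 in wild type and 241 in pubs hy2. The counts for independent lists are therefore likely too low, and the excess over them too large. The pairs of libraries behind these lists have no library in common. Each pair sets a time 0 dark library against a later one, so the overlap may also reflect the elapsed hour. The median log2 fold of the 912 genes was 1.47 in wild type and 0.58 in pubs hy2, above all of 10000 random lists matched on expression (-0.05 to 0.06). That of the 846 genes was -1.36 in wild type and -0.17 in pubs hy2, below all of the random lists (-0.06 to 0.08). Lists chosen by their fold in 1 genotype tend to show smaller folds in the other, and the reverse choice gave this as well. The 630 genes higher in pubs hy2 had a median log2 fold of 1.29 there and 0.66 in wild type, and the 261 lower genes -1.20 and -0.26. Across all 16706 genes, the correlation of the folds was 0.340 (Pearson) and 0.303 (Spearman), across genes that are not independent replicates.

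**Figure D2:**
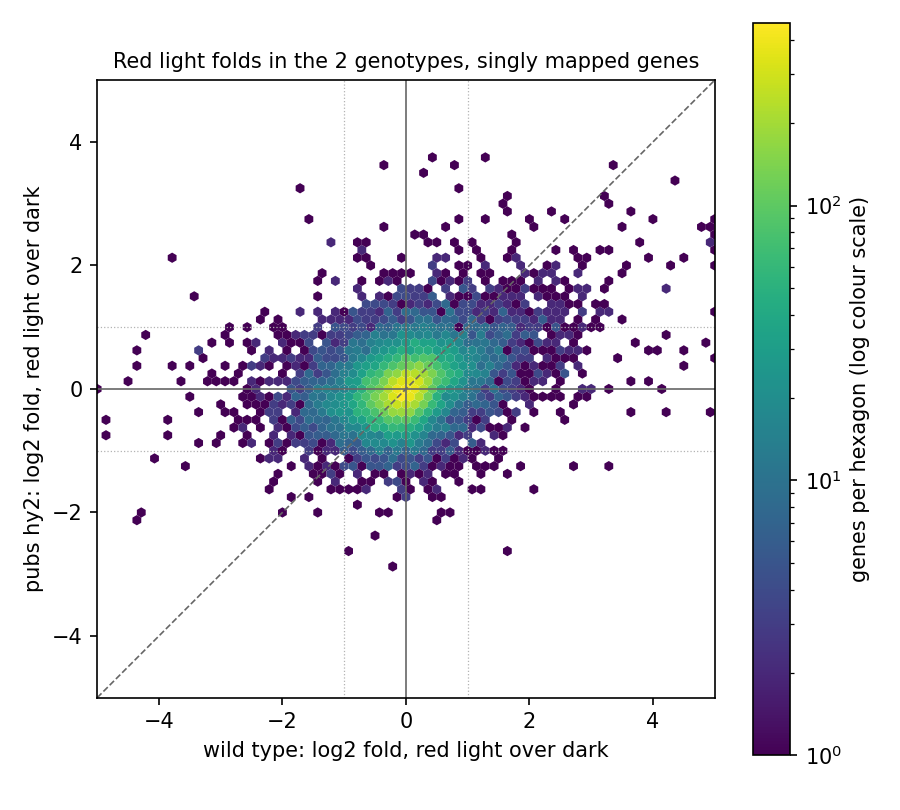
Each hexagon counts singly mapped genes by log2 fold of red light over dark in wild type (x axis) and in pubs hy2 (y axis), on a log colour scale, for 16706 genes with at least 50 reads in each pair of libraries. The dashed line marks equal folds, the dotted lines 2-fold differences, and 9 genes beyond the axis limits are drawn at the edge. The spread along the wild-type axis exceeds that along the pubs hy2 axis, and genes with high wild-type folds lie mostly above 0 but under the dashed line.

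The ratio of the red light fold in pubs hy2 to that in wild type differed from 1 by the size rule in 2841 of 19825 measured genes, 1651 with a ratio above 1 and 1190 with a ratio below 1. With an assumed biological coefficient of variation of 0.2 in each library, it was 1828 genes, 1066 above and 762 below. The additive fit estimated 0.239, but its error includes these same differences between genotypes, so it does not check the assumed value. By the size rule without that assumption, 1530 of 18654 singly mapped genes had a ratio above 1 and 1035 a ratio below 1. Of the 912 genes higher in red light in wild type, 453 (49.7%) had a smaller fold in pubs hy2 by this ratio and 7 had a larger one. Of the 846 lower genes, 567 (67.0%) were less reduced, or not reduced, in pubs hy2, and 0 were reduced more. With the assumed variation the numbers were 343 of 912 (37.6%) and 442 of 846 (52.2%). These shares rest on the same wild-type libraries that chose the genes. The 56 genes with a wild-type log2 fold of at least 3 had medians of 3.71 in wild type and 1.42 in pubs hy2, and 37 of them were also higher in pubs hy2. The 31 genes with a log2 fold of -3 or less in wild type had medians of -3.59 and 0.10, and 4 of them were also lower in pubs hy2.

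Single genes ran in opposite directions, though some differed little in pubs hy2. The singly mapped gene with the highest ratio, Pp1s53_125V6, had 57 reads in the dark and 5 in red light in wild type, and 39 and 271 in pubs hy2. The ratio of its folds was 70.6 (interval 25.8 to 234.7). The one with the lowest ratio, Pp1s1_366V6, had 1 and 98 reads in wild type and 577 and 698 in pubs hy2, a ratio of 0.0110 (0.000275 to 0.0632). This gene is 0.162 kb long, against a median of 1.75 kb for singly mapped measured genes. After scaling, its fold in pubs hy2 was 0.791 (0.708 to 0.885). Over all genes, multi-mapping genes led. Pp1s292_31V6 had 3711 and 0 reads in wild type and 2657 and 4773 in pubs hy2, a ratio of at least 1979, and Pp1s442_5V6 had 324 and 1110 reads in wild type and 1292 and 0 in pubs hy2, a ratio at least 1656-fold below 1.

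More genes differed between the genotypes than between the light conditions. In the dark, 2507 genes were higher and 1941 were lower in pubs hy2 than in wild type, 24.4% of 18266 measured genes, and among singly mapped genes 2293 and 1776 of 17231. The split between higher and lower depended on the scaling: with the 100 most abundant genes left out of the library totals and no TMM factors, 2124 genes were higher and 2659 lower. Scaling by library totals alone moved the median log2 fold of measured genes from -0.08 to -0.18. Differences of at least 8-fold were mostly increases in the mutant, with 459 singly mapped genes higher and 49 lower. The highest folds were those of Pp1s129_85V6, with 3 reads in wild type and 2836 in pubs hy2, 1185-fold higher (405.0 to 5749), and Pp1s20_253V6, with 6 and 3857 reads, 805.8-fold higher (369.9 to 2197). Both were singly mapped. The singly mapped gene with the lowest fold, Pp1s219_85V6 (length 0.177 kb), had 109 and 2 reads, a fold of 0.0230 (0.00275 to 0.0851). Over all genes it was the multi-mapping Pp1s365_24V6, with 3958 and 1 reads and a fold of 0.000317 (8.0e-06 to 0.00177).

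In red light, 2924 genes were higher and 2011 were lower in pubs hy2 than in wild type, 26.2% of 18868 measured genes, and among singly mapped genes 2700 and 1796 of 17785. With 0 reads set to the floor of 3 counts, the singly mapped gene with the highest fold was Pp1s25_135V6, which had 26 reads in wild type and 37967 in pubs hy2, 1630-fold higher (1113 to 2496). The next had 0 and 3405 reads, at least 1267-fold higher, so its fold may be the larger. In the dark Pp1s25_135V6 had 35 and 19445 reads, 696.4-fold higher (500.5 to 1000.1). The one with the lowest fold, Pp1s55_88V6, had 308 and 4 reads, a fold of 0.0145 (0.00393 to 0.0375). Over all genes the multi-mapping Pp1s292_31V6 led, with 0 and 4773 reads, at least 1776-fold higher, and Pp1s365_24V6, with 5207 and 0 reads, was at least 1555-fold lower.

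Genotype differences in the dark mostly kept their direction in red light. Genes higher in pubs hy2 passed the size rule again more often than lower genes. Of 2258 singly mapped genes higher in pubs hy2 in the dark, 1703 (75.4%) were also higher in red light, where independent lists would share 328.9, and 14 were lower. Of 1739 lower genes, 753 (43.3%) were also lower in red light, where independent lists would share 167.1, and 43 were higher. The lower genes lay nearer the 2-fold limit, with a median log2 fold of -1.35 in the dark against 1.74 for the higher genes. In red light 88.6% of the lower genes kept their direction, with a median of -0.88. Of the higher genes 95.7% did, with a median of 1.65. These counts for independent lists again ignore expression level. The correlation of the folds across 17110 genes was 0.805 (Pearson) and 0.730 (Spearman). In both light conditions 162 singly mapped genes were at least 16-fold higher in pubs hy2 and 0 were at least 16-fold lower. At 8-fold the numbers were 309 and 7.

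**Figure D3:**
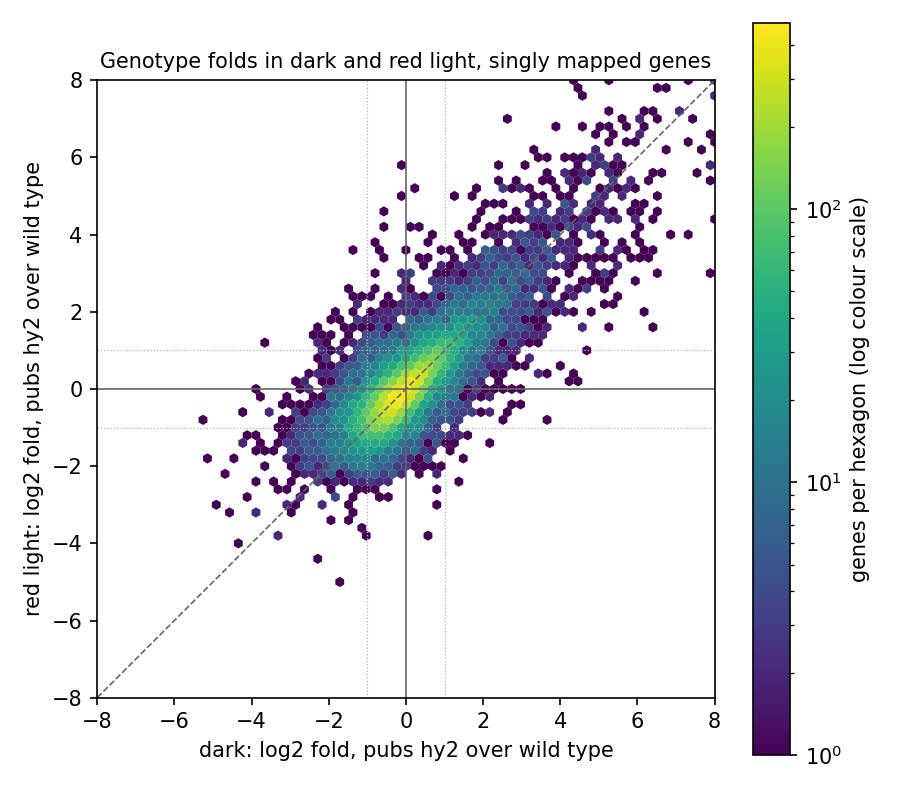
Each hexagon counts singly mapped genes by log2 fold of pubs hy2 over wild type in the dark (x axis) and in red light (y axis), on a log colour scale, for 17110 genes with at least 50 reads in each pair of libraries. The dashed line marks equal folds, the dotted lines 2-fold differences, and 11 genes beyond the axis limits are drawn at the edge. Genes follow the dashed line, with a correlation of 0.805, and reach farther on the side higher in pubs hy2.

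Effects common to both genotypes, or to both light conditions, were tested with 2 libraries on each side. In the additive fit of genotype and light, edgeR's quasi-likelihood test found 4707 of 20409 genes differing between genotypes at an adjusted p under 0.05, 2853 higher and 1854 lower in pubs hy2. For red light it found 0 genes, with 2183 at an unadjusted p under 0.05 and a smallest adjusted p of 0.104. DESeq2 found 416 genes for red light, 334 higher and 82 lower, and limma on log2 RPKM found 0 with either pseudocount, with 2465 genes (pseudocount 0.1) and 2358 genes (pseudocount 1) at an unadjusted p under 0.05. Without a filter on low counts edgeR found 94 genes, 87 higher and 7 lower in red light. On singly mapped genes it found 20, and these 20 were higher. A light response that differs between genotypes enters the error of this model. Nothing in the labels says whether the libraries came from separate cultures, so these p-values measure only the spread between these libraries.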

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

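Chosen only after the result was seen were the tests on singly mapped genes, on the depth of and genomic DNA in the pubs hy2 libraries, and on matched read numbers, the last of which replaced a comparison of median reads (467.5 for multi-mapping and 490 for singly mapped genes that differed) that did not separate the alternatives. Among the genes named above, 7 had red light folds in opposite directions in the genotypes, each beyond its counting interval; with 1 library per group the difference was not tested against replicates. As log2 ratios of the fold in pubs hy2 to that in wild type, the values were 6.14 for Pp1s53_125V6, 3.58 for Pp1s219_85V6, 1.23 for Pp1s25_135V6, -4.81 for Pp1s129_85V6 and -6.51 for Pp1s1_366V6. The multi-mapping genes Pp1s292_31V6 and Pp1s442_5V6 had 10.95 and -10.69, computed with 0 reads set to 3 counts. The red light fold in pubs hy2 was near 1 for Pp1s1_366V6 (0.791), Pp1s129_85V6 (0.796), Pp1s25_135V6 (1.28) and Pp1s292_31V6 (1.18). For these genes the opposite direction in pubs hy2 was a small difference. The genes were picked for extreme folds, so extreme ratios among them carry no weight beyond their counting intervals.

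Genes with at least 90% multi-mapping reads made up 19 of the 50 largest red light folds in wild type. A shift of reads between near-identical copies from library to library could produce such folds, and summing copies should then cancel them. For the 54 such genes that differed and had another multi-mapping gene of exactly equal length, the median absolute log2 fold was 2.05 singly and 0.73 after summing genes of equal length, below all 1000 sums over randomly drawn multi-mapping genes (0.99 to 1.84). Low read numbers are argued against: 32.0% of the 244 measured multi-mapping genes differed, above all 1000 draws of singly mapped genes matched on reads (6.97% to 20.9%). True differences between copies stay open for the part that summing did not remove. For the part removed they stay open too, because summing also cancels true opposite changes of copies.

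The dark libraries of the genotypes differed in 2.10 times as many genes as the wild-type libraries did after red light. Unequal depth is argued against, since the ratio was 2.23 with all libraries thinned to equal depth. Reads shared between copies are argued against, since it was 2.10 among singly mapped genes. The mutations are the biological explanation the design names. The additive fit tested genotype with 2 libraries on each side (4707 genes), and that test does not separate the mutations from other differences between the lines or their cultures.

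At least 50 reads in both pubs hy2 libraries and at most 3 in each wild-type library were found for 38 singly mapped genes. The opposite was found for 0 singly mapped genes. Genomic DNA in the mutant libraries is argued against: it would give reads to nearly all genes, and of 8308 singly mapped genes without reads in wild type, 6.52% had reads in both pubs hy2 libraries. Greater depth is argued against, since the pubs hy2 libraries held fewer gene reads than wild type, 0.860 times in the dark and 0.935 times in red light. Reads from another organism were not tested. The mutations, the biological explanation the design names, were not separated from other differences between the lines or their cultures.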

How the results depend on the processing

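Chosen only after the data were seen were the alternatives on singly mapped genes, the assumed variation for genes with a smaller red light difference in pubs hy2, the thinning for the genes found in 1 genotype (33 against 38 as reported), and the form of the abundance alternative (no TMM factors) that also leaves the 100 most abundant genes out of those counted; the planned form was rewritten to keep them after this form had been run, and their counts differed little (2139 and 2125 genes in wild type after red light). No paired analysis was possible because each group had 1 library and no replicate numbers to pair; the additive fit carries the other factor as a term. No alternative could be run for the gene lists, which had no members. Counts of genes by the size rule stayed within 1.5 times of those reported under every scaling, the authors' RPKM, a minimum of 20 reads, equal depth and singly mapped genes. With no minimum of reads, 3185 genes differed after red light in wild type and 2430 in pubs hy2, and with a minimum of 200 reads 593 did in pubs hy2. A fold of at least 3 left 826 genes in wild type and 321 in pubs hy2 after red light, 2101 between genotypes in the dark, 2330 in red light and 1373 for the ratio of folds, fewer by construction. An assumed biological coefficient of variation of 0.2 left 1828 genes for the ratio of folds. For red light in the additive fit, 0 genes became 94 without a filter on low counts, 20 on singly mapped genes and 416 with DESeq2; the cause was not tested. The genotype count of that fit lay between 3556 and 5177. Over TMM, library totals, DESeq2 factors, upper quartiles, totals without the 100 most abundant genes and the authors' RPKM, the share of higher genes ran from 48.3% to 53.1% for red light in wild type, 62.1% to 66.9% in pubs hy2, 44.4% to 59.4% between genotypes in the dark, 52.3% to 59.7% in red light and 55.0% to 63.5% for the ratio of folds. Of 100 values of named genes under alternatives, 0 changed direction and 23 left their counting interval, all 23 on log2 RPKM with a pseudocount. Depth limits folds of genes at 0 reads to bounds.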

Other observations

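The single gene described here, the count of pairs 3 places apart and the reading of calls by length were chosen after related results were seen. The singly mapped gene with the largest red light fold in wild type among those with at least 1000 reads, Pp1s370_29V6, had 51 reads in the dark and 3966 in red light, 57.1-fold higher (95% counting interval 43.3 to 76.8). In pubs hy2 it had 248 and 1930 reads, 5.09-fold higher (4.46 to 5.83). The wild-type fold was 11.2 times (8.22 to 15.5) that of the mutant. In the dark it was 6.10-fold higher in pubs hy2 than in wild type (4.49 to 8.41), and in red light its level in pubs hy2 was 0.543 of that in wild type (0.514 to 0.574).

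The 38 singly mapped genes found in pubs hy2 libraries had between 50 and 434 reads in the dark and between 56 and 570 in red light. Their median length was 0.534 kb, against 1.75 kb for singly mapped measured genes, which were not matched to them on reads.

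Genes with consecutive identifiers may share a response, under the assumption that identifiers number genes along a sequence. Among singly mapped genes, 104 consecutive pairs differed in the same direction after red light in wild type, against a median of 64 in 1000 redraws matched on reads (41 to 87). Between genotypes in the dark there were 445 such pairs, against 284 (231 to 330). Reads shared between overlapping or adjoining gene models could also give consecutive pairs, and would give no excess 3 places apart. At that distance 60 pairs were found after red light, at percentile 51.8 of the redraws, and 286 between genotypes, at percentile 92.9, so shared reads stay open for both.

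With singly mapped genes in 5 equal bins by length, the median log2 fold after red light in wild type of the longest bin minus that of the shortest was -0.041. Among genes that passed the size rule, 289 were higher and 189 lower in the shortest bin (60.5% higher), and 132 and 175 in the longest (43.0% higher). After red light in pubs hy2, 213 were higher and 137 lower in the shortest bin, and 92 and 41 in the longest. Higher genes thus outnumbered lower ones in both bins there. A length bias in the wild-type comparison stays open, since the median over all genes does not cover the genes with large folds.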
